A study of Mus musculus with 384 samples.

How the data were processed

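RNA was measured in single sorted granulocyte/macrophage progenitors (GMPs) from mouse bone marrow. The labels give 384 samples, each 1 well of a 96-well plate, in 4 sets: BCR-ABL replicates 1, 2 and 4 and 1 control set. Cells were sorted as lineage-negative, c-Kit-positive, Sca-1-negative, CD34-positive and FcγR-positive, and libraries came from SMART-seq2 cDNA with a Nextera XT kit, per the labels' protocols. The deposited values are counts of reads per Ensembl gene, 1 column per well, not normalised. Per the submitters' processing notes, the authors used GSNAP 2015-09-29, HTSeq 0.5.3p3 and the mm10 build. The annotation release, the strand setting and any filter on reads are not given in the sources used here. SMART-seq2 reads carry no molecular identifiers, so reads are not independent molecules and the intervals below cover counting error only. Without a stated strand setting, overlapping and antisense genes cannot be told apart.

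The tables hold 46078 gene rows, 92 spike-in rows and 5 summary rows. Symbols and positions came from GENCODE vM21, built on the same mm10 assembly, which matched 45143 gene identifiers and left 935 without a symbol. Of all reads, 44.9% lay on genes, 40.9% were not aligned, 7.7% were outside features, 6.2% were ambiguous and 0.26% came from spike-ins. Spike-in and summary rows stayed out of library sizes and tests. Wells with at least 50000 reads on genes and 1000 genes with a read were kept, which left 323 of 384. Each well was sorted to hold 1 cell and no doublet caller was run. Kept cells had between 50434 and 4758711 reads on genes, with a median of 1483694. For shares of cells with a transcript and for scores per cell, each cell was thinned to 674952 reads, the 10 percentile of kept cells, which left out 33 cells.

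Cells are not replicates, so raw counts were summed over the kept cells of each set, and 3 BCR-ABL sums were compared with 1 control sum. The test was edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 2 residual degrees of freedom, all from the BCR-ABL sets, and the lone control set is assumed to vary like them. Condition and set cannot be told apart for the control. The labels do not say whether the sets are separate animals. Sex-linked transcripts, given below, show that BCR-ABL replicate 1 cannot come from the same animal as replicates 2 and 4. Whether replicates 2 and 4 are separate animals is not known. The p-values thus measure only the spread between these sets, part of which may be technical. The biological coefficient of variation was 0.68. On simulated counts with the means, depths and spread of these sums, this test recovered 9.0% of 67 genes changed by a log2 value of 1, 58.2% of 67 changed by 2 and 83.3% of 66 changed by 4, with 12 false calls among 19311 genes. With a coefficient of variation of 0.1 it recovered all of them, with 9 false calls. DESeq2 1.42.0 recovered 35.8%, 79.1% and 97.0% with 208 false calls, and made 134 false calls where no gene had been changed, against 3 by edgeR. A simulated list of 30 genes raised by a log2 value of 1 had a fry p of 0.0252, and a random list had 0.996.

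Gene lists (36) and cell type markers were fixed before the data were examined, as were the tests, the filters on cells and the rule for named genes. The rule takes the 12 genes with the largest change in each direction past the test, or, where fewer than 5 pass, the 5 with the smallest p, detected in at least 25% of the cells of a set, with all 3 BCR-ABL sets on the same side of the control and without predicted genes or pseudogenes. It adds up to 4 members of each list with the smallest p and a fixed set of genes of the gate, of the transgene and of myeloid fate. It gives 151 genes, of which 60 were picked for the text after their values had been seen. Values of some single genes are not reported here. Lists were tested with limma 3.58.1. Here fry asks whether members move, on balance, one way, and its mixed form whether they change in either direction. camera compares the list with other genes, with a preset correlation of 0.01 or an estimated one.

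Cells were clustered with leidenalg 0.10.2 (resolution 1.0, 15 neighbours, 20 principal components of 1500 variable genes). Clusters were named from the fixed markers, and the scoring rule was set after the clusters had been seen. A named cluster needed a mean marker difference of at least 0.5 on the log2 scale, at least 3 markers detected in 25% of its cells, and more of its own than of another type's markers among its 10 leading genes. Within a class, counts were summed per set where each set held at least 10 cells. Only neutrophil-like cells met this, so the planned test of monocyte-like cells and of the interaction between class and condition could not be run on all sets. Intervals of shares are exact (Clopper-Pearson) at 95%.

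Alternatives fixed in advance were another normalisation (RLE), no filter on low counts, DESeq2, limma on mean log2(CPM + 1), library sizes without the 20 genes with most reads, other filters on cells, thinned cells, each BCR-ABL set left out, other clustering settings and unthinned scores. Filters on detection at 25%, 50% and 90% of cells, a second low-value filter in limma, removal of 1 cell, clustering without some genes or on thinned cells, and tests without BCR-ABL replicate 4 were added after the data had been seen. Other tools were Python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9.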

Results

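Granulocyte/macrophage progenitors (GMPs), the marrow cells that give rise to neutrophils and monocytes, were profiled one by one from C57Bl/6 mice. The mouse model carries an inducible BCR-ABL transgene, and the labels name the treatment of each set as BCR/ABL induction or control. For all sets the sources list doxycycline at 20 mg per L, induction at 5 weeks of age and analysis 5 to 6 weeks after induction. BCR-ABL is the fusion oncogene of chronic myeloid leukaemia, and here it is expressed once doxycycline is withdrawn. Of 96 wells per set, 76, 61 and 92 cells were kept in BCR-ABL replicates 1, 2 and 4, and 94 in the control set. The sums over kept cells held 126.2, 121.4, 141.0 and 139.7 times 1e6 reads on genes. Median reads per kept cell were 1649313, 2084608, 1385349 and 1200639, and median genes per cell were 9392, 9616, 9355 and 9055. Sets also differed in sex-linked transcripts: Xist reached 5 CPM (reads per 1e6 reads on genes) in 75 of 76, 0 of 61, 3 of 92 and 94 of 94 cells in the same order, so BCR-ABL replicates 2 and 4 differ from the other sets in this respect.

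The first question was which transcripts differ between BCR-ABL and control GMPs. Values are sums over all cells of a set. Lrg1, a secreted glycoprotein of neutrophil granules (ENSMUSG00000037095, mm10 chromosome 17, 56119678 to 56122001), stood at 35.4 ± 2.58 CPM (SD, n = 3) against 3.78 in the control, a log2 fold change of 3.23 (SE 0.26). Wfdc21 stood at 74.1 ± 13.6 CPM against 8.55. Ccno, a cyclin-like protein needed for multiciliated cells (ENSMUSG00000042417, chromosome 13, 112987802 to 112990777), stood at 16.4 ± 4.26 CPM against 0.071, which rests on 10 reads in the control. Far2, which reduces fatty acyl-CoA to alcohols, had a log2 fold change of 2.30 (SE 0.27), and the ribosomal protein gene Rpl3 one of 1.63 (SE 0.19). On the lower side stood Cd34, the stem and progenitor surface protein used in the sort (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279), with 162 ± 17.5 CPM against 436. Mpeg1, a pore-forming protein of macrophages (ENSMUSG00000046805, chromosome 19, 12460779 to 12465283), stood at 35.4 ± 7.57 CPM against 172. Cd93, Ncf4 (a subunit of the phagocyte oxidase) and Ppfia4 had log2 fold changes of -1.30, -1.32 and -2.98.

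These 10 genes had the smallest p-values in each direction under the rule for named genes, and none passed the test. Of 20324 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p was 0.594, and 1459 had an unadjusted p under 0.05. DESeq2 on the same sums called 562 genes, 395 higher and 167 lower, and limma called 0, with 1347 at an unadjusted p under 0.05. The values below are therefore sizes with their spread over 3 BCR-ABL sets and 1 control set. DESeq2 called 47 of the 151 genes under the rule, and 34 of the 60 that were picked from these for the text after their values had been seen.

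Early neutrophil precursors fill their primary granules with proteases. All 16 measured genes of the primary granule and early neutrophil list, Cebpe and Gfi1 among them, had a positive log2 fold change (median 0.64), 11 had an unadjusted p under 0.05, 11 passed when adjusted over the list alone, and 0 passed over all genes tested. Elane, neutrophil elastase, stood at 18013 ± 969 CPM (SD, n = 3) against 12853, and Prss57, a related protease, at 643 ± 89.1 against 263. Serpinb1a, an inhibitor of such proteases, had a log2 fold change of 0.82 (SE 0.13), while Mpo, myeloperoxidase, had one of 0.00 (SE 0.06). Cebpe and Gfi1, transcription factors of granulocyte maturation, had log2 fold changes of 1.09 (SE 0.24) and 1.49 (SE 0.42). Late granule genes had a median log2 fold change of 1.49 over 16 members, of which 13 were positive, 7 higher and 1 lower at an unadjusted p under 0.05, and 6 higher and 1 lower when adjusted over the list alone. Lcn2, an iron-binding granule protein, stood at 401 ± 128 CPM against 45.7 and S100a8, a calcium-binding protein of neutrophils and monocytes, at 430 ± 96.0 against 142. Lyz2, lysozyme, was the 1 lower member, at 373 ± 96.1 against 927. Neither list passed fry (adjusted p = 0.271 for the primary granule list). Against other genes, camera with a preset correlation gave adjusted p = 2.7e-11 for primary and 2.59e-05 for late granule genes. No list passed with an estimated correlation (smallest adjusted p = 0.621).

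Of the monocyte genes, 17 of 18 measured members had a negative log2 fold change (median -1.58), 8 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. Irf8, the transcription factor that directs GMPs to monocytes (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694), stood at 264, 424 and 61.4 CPM in the 3 BCR-ABL sets against 980, a log2 fold change of -1.97 (SE 0.93, p = 0.0933). Csf1r, the receptor for macrophage colony-stimulating factor, stood at 99.8, 132 and 49.7 CPM against 294. Psap, a lysosomal protein, and Cst3, a protease inhibitor, had log2 fold changes of -1.29 (SE 0.22) and -0.64 (SE 0.13), and Cx3cr1 and Irf5 of -2.65 and -1.53. The list passed camera with a preset correlation (adjusted p = 2.7e-11), but not with an estimated one (adjusted p = 0.621) and not fry. Within neutrophil-like cells its median was 1.71, with 13 of 15 members positive. Monocyte genes were not kept out of the clustering that made this class, and Irf8 was among the leading genes of each cluster named monocyte-like. The control cells of the class may thus have been selected for low monocyte transcripts. This median therefore does not show a rise of monocyte genes in BCR-ABL cells. Interferon response genes had a median of -0.54, with 30 of 34 negative, 10 lower and 1 higher at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Irf9 and Gbp2 had log2 fold changes of -1.37 (SE 0.24) and -1.40 (SE 0.30), against 2.45 (SE 0.45) for Ifitm1. Mx1 had 881 reads in the control, all in 6 cells and 52.6% of them in 1 cell. The interferon list passed the mixed form of fry (adjusted p = 0.0327) and camera with a preset correlation (2.2e-08, adjusted p = 0.621 with an estimated correlation). Macrophage genes passed both as well (0.0327 and 4.62e-04, adjusted p = 0.621 with an estimated correlation). Both mixed calls ended with thinned cells (interferon 0.103, macrophage 0.107), without 1 cell of BCR-ABL replicate 4 (0.0503 each), and without replicate 1 (0.356, 0.460), 2 (0.207, 0.129) or 4 (0.191, 0.186). With detection in 25% of cells the interferon call stood (1.16e-03), while 3 macrophage genes were left, with a median of 1.07 in place of -3.56. Where the mixed calls ended, the medians stayed negative. For interferon genes they were -0.60 with thinned cells, -0.54 without the 1 cell, and -0.66, -0.53 and -0.53 without replicates 1, 2 and 4. For macrophage genes they were -4.11, -3.56, -2.98, -3.02 and -6.04 in the same order. The macrophage genes had few reads: C1qc had 131 reads in the control, 99.2% of them in 1 cell, and 0 in the BCR-ABL sets. C1qa had 79 reads in the control and 0 in the BCR-ABL sets, Cd5l had 130, all in 1 control cell, and Spic 123, 90.2% of them in 1 control cell.

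**Figure D1:**
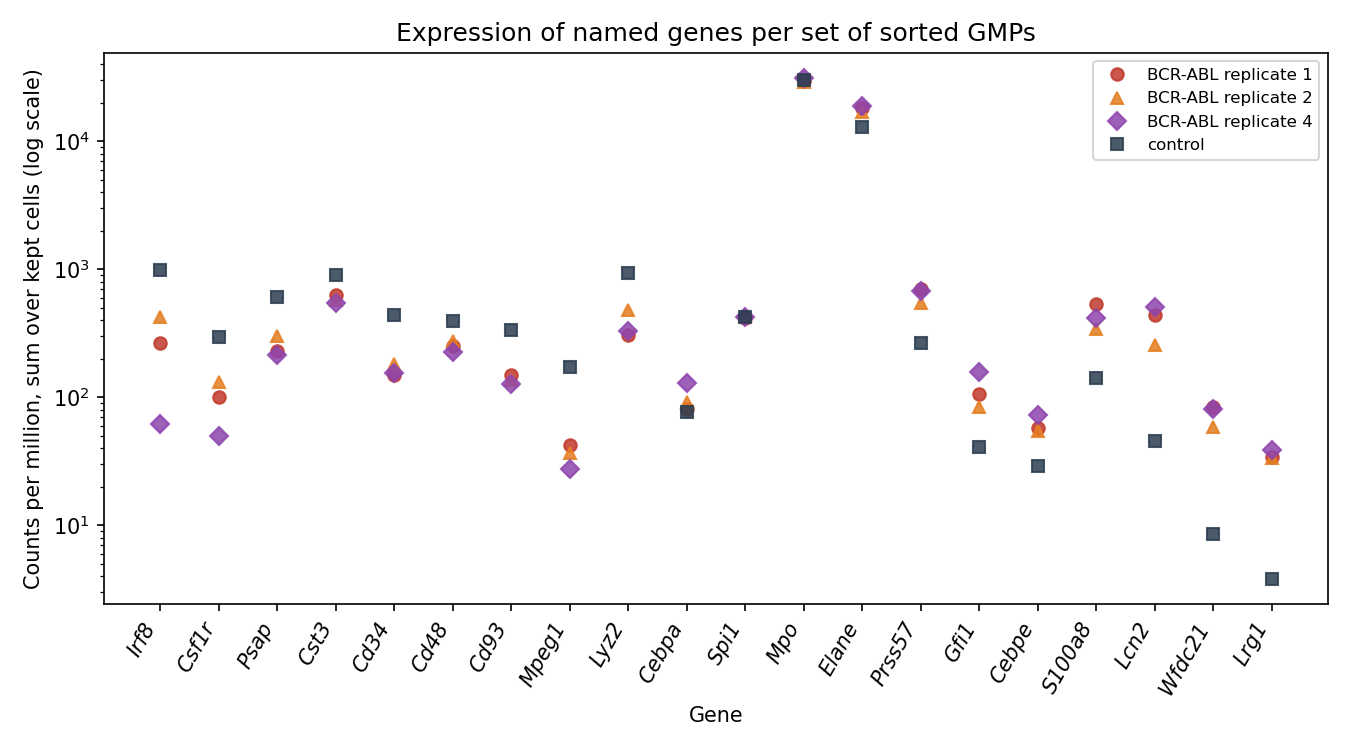
CPM on a log axis for 20 named genes, with 1 point per set: BCR-ABL replicates 1, 2 and 4 and the control. Irf8 lies at 264, 424 and 61.4 CPM in the BCR-ABL sets against 980 in the control, and Lcn2 at 442, 258 and 504 against 45.7.

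Of the genes that define the sort, Cd34 had a log2 fold change of -1.43, while Kit stood at 0.19 (SE 0.19), Fcgr3 at 0.09 (SE 0.17) and Ly6a, which encodes Sca-1, at 1.15 (SE 0.69). Cd48, a surface protein outside the sort, stood at -0.64 (SE 0.16). Among regulators of myeloid fate, Cebpa had a log2 fold change of 0.39 (SE 0.32), Spi1 of -0.01 (SE 0.12), Zeb2 of -0.86 (SE 0.15) and Myc of 0.43 (SE 0.14). Gata2 and Meis1, of early progenitors, stood at -0.71 (SE 0.97) and -0.47 (SE 0.22), and Ctnnb1, beta-catenin, at -0.08 (SE 0.18). The mouse genes of both fusion partners had log2 fold changes of -0.19 (Abl1, SE 0.18) and -0.33 (Bcr, SE 0.24), and these counts do not separate the human transgene from them. Bcl2, which restrains apoptosis, stood at -1.70 (SE 0.28) and Casp8, an initiator caspase, at -0.57 (SE 0.18). Slc16a3, a lactate transporter, stood at 2.37 (SE 0.40), the glycolytic enzyme gene Gpi1 at 0.45 (SE 0.16), and Selplg and Itgal, which serve leukocyte adhesion, at -1.28 (SE 0.28) and -0.94 (SE 0.14).

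Erythroid genes (median log2 fold change -1.54, 11 of 14 negative) and cholesterol synthesis genes (median 0.25, 14 of 23 positive, among them Hsd17b7 at 1.98) passed camera with a preset correlation only, with adjusted p = 1.93e-03 and 0.0204. Of the 14 erythroid genes, 10 had a read in under 10% of the cells of each set, 8 of these negative, and the other 4 had a median of -0.60. The other 29 lists passed no test, with a smallest adjusted p of 0.271 by fry, 0.0618 by its mixed form and 0.0546 by camera. Among cell type lists the median log2 fold change was -0.10 for stem and early progenitor genes, 0.06 for myeloid transcription factors, -0.27 for megakaryocyte, -0.09 for basophil and mast, -0.43 for dendritic, -0.21 for lymphoid and 3.23 for the 4 stroma and endothelium genes. Without members read in under 10% of the cells of each set, the sign turned for megakaryocyte (0.24), dendritic (0.02) and lymphoid genes (0.11). It held for stem (-0.09), myeloid transcription factor (0.09) and basophil and mast genes (-0.06), and no stroma and endothelium gene was left. Eosinophil genes had a median of 5.35, which was not computed without BCR-ABL replicate 4, where Epx had 99.4% of its reads in 1 cell. Among signalling lists the median was 0.08 for STAT5 targets, 0.33 for MAPK feedback, -0.003 for Wnt and beta-catenin, 0.26 for NF-kB, 0.11 for TGF-beta signalling, -0.03 for cytokine receptors and 0.12 for adhesion. Of the STAT5 targets, Cish and Socs3, feedback inhibitors of cytokine signalling, stood at 2.63 (SE 1.04) and 4.09 (SE 1.36). The medians were -0.12 for S phase, -0.05 for G2/M, 0.14 for glycolysis, -0.05 for oxidative phosphorylation, 0.22 for the unfolded protein response, 0.24 for p53 targets, -0.01 for apoptosis regulators and 0.13 for MYC targets. They were 0.04 for ribosomal proteins, 0.10 for mitochondrially encoded genes, -0.02 for dissociation genes, 0.06 for gate genes, -0.26 for both transgene parents and 9.38 for sex-linked transcripts, which follow the difference in sex-linked transcripts between sets. Median and mean or test differed in sign for gate genes, stem genes, myeloid transcription factors, basophil and mast, dendritic, lymphoid, NF-kB, TGF-beta, cytokine receptor and adhesion genes.

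The next question was how cells of each kind were shared out. Monocyte-like cells made up 28.9%, 45.9% and 5.4% of kept cells in the 3 BCR-ABL sets (22, 28 and 5 cells) against 77.7% in the control (73 cells), a mean of 26.7% ± 20.3 (SD, n = 3). When thinned cells were clustered, these shares were 6.2%, 16.7% and 1.2% against 68.9%. The BCR-ABL shares depend on the name of 1 cluster, led by Ung and Ifitm1. It held 14, 17 and 5 cells of BCR-ABL replicates 1, 2 and 4 and 5 control cells. Irf8 was the only monocyte marker among its 10 leading genes. With thinning, a cluster also led by Ung and Ifitm1 (14, 17, 6 and 5 cells) had no such marker there and stayed unnamed. Neutrophil-like cells made up 44.7%, 31.1% and 66.3% (34, 19 and 61 cells) against 14.9% (14 cells), a mean of 47.4% ± 17.8. This share was 23.7% against 7.4% at a clustering resolution of 0.5, and 23.1% against 7.4% when cell cycle genes were left out of clustering. The exact 95% interval of the control, 67.9 to 85.6% for monocyte-like cells, lay above those of all 3 BCR-ABL sets, the highest of which ended at 59.2%. Without genes at an unadjusted p under 0.05 or called by DESeq2 in clustering, BCR-ABL replicate 2 stood at 52.5% (39.3 to 65.4%) against 70.2% (59.9 to 79.2%) in the control, and these intervals overlap. Cells of 2 clusters without a name made up 25.9% ± 2.7 against 7.4%. The cluster of 29 cells had few reads, a median of 0.28 times that of their set, with Slc34a2 among its leading genes. The cluster of 38 cells scored highest for early progenitor markers (1.01), but 1 marker of another type was also among its leading genes. The smallest exact permutation p of 1 set against 3 is 0.25, and no test was run on these shares. Most control monocyte-like cells, 68 of 73, lay in 2 clusters, 1 of which held 35 control cells among 38 and had Xist among its leading genes. With each gene centred within its set, which removes differences between set means, the monocyte-like difference turned from -51.0 to 12.4 points.

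**Figure D2:**
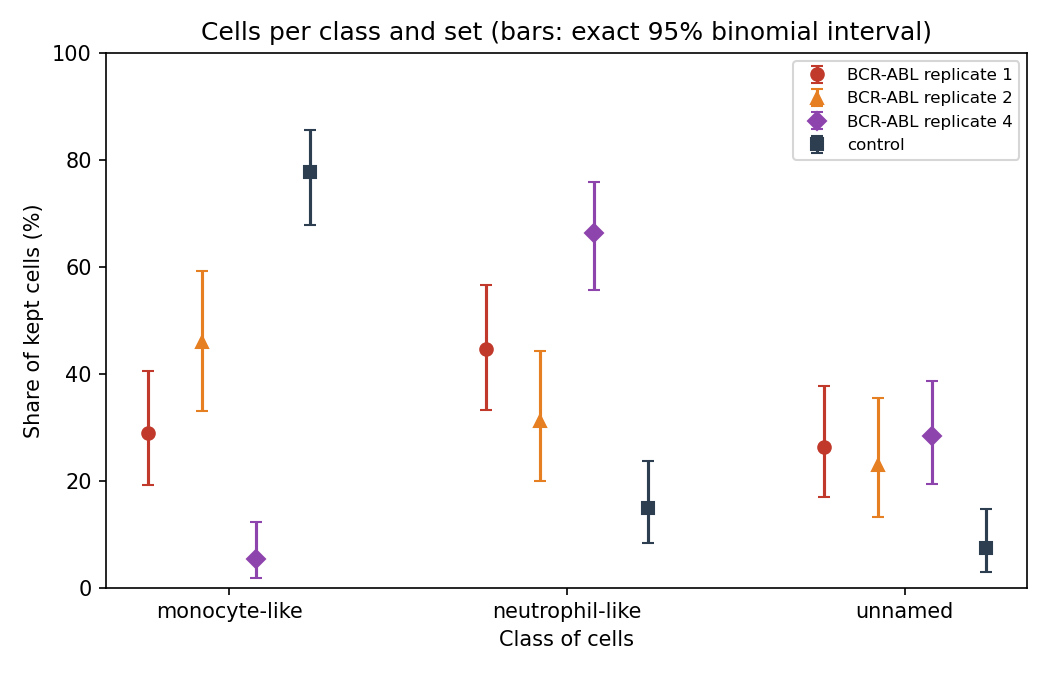
Share of kept cells (%) by class and set, with exact 95% binomial intervals as bars. Monocyte-like cells span 5.4 to 45.9% in the BCR-ABL sets against 77.7% in the control, and neutrophil-like cells 31.1 to 66.3% against 14.9%.

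Irf8 and Gfi1 oppose each other in the choice between monocyte and granulocyte fates, and were followed in single cells thinned to equal depth. At least 10 Irf8 reads were found in 41.5%, 63% and 19.8% of BCR-ABL cells against 84.4% of control cells, and at least 10 Gfi1 reads in 73.8%, 64.8% and 92.6% against 40%. Cells with Irf8 alone made up 21.5%, 29.6% and 1.2% against 55.6%, and cells with Gfi1 alone 53.8%, 31.5% and 74.1% against 11.1%. Both transcripts were found together in 20.0%, 33.3% and 18.5% of cells against 28.9%. The limit of 10 reads was chosen after the data had been seen. Carry-over between wells at the rate seen for Prg2, a gene chosen after its values were seen, would bring 2.2, 3.4 and 0.6 Irf8 reads to an unthinned well of the BCR-ABL sets and 9.2 in the control, close to the limit. Median Irf8 in kept cells was 3.11, 84.7 and 0.0 CPM against 848.

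**Figure D3:**
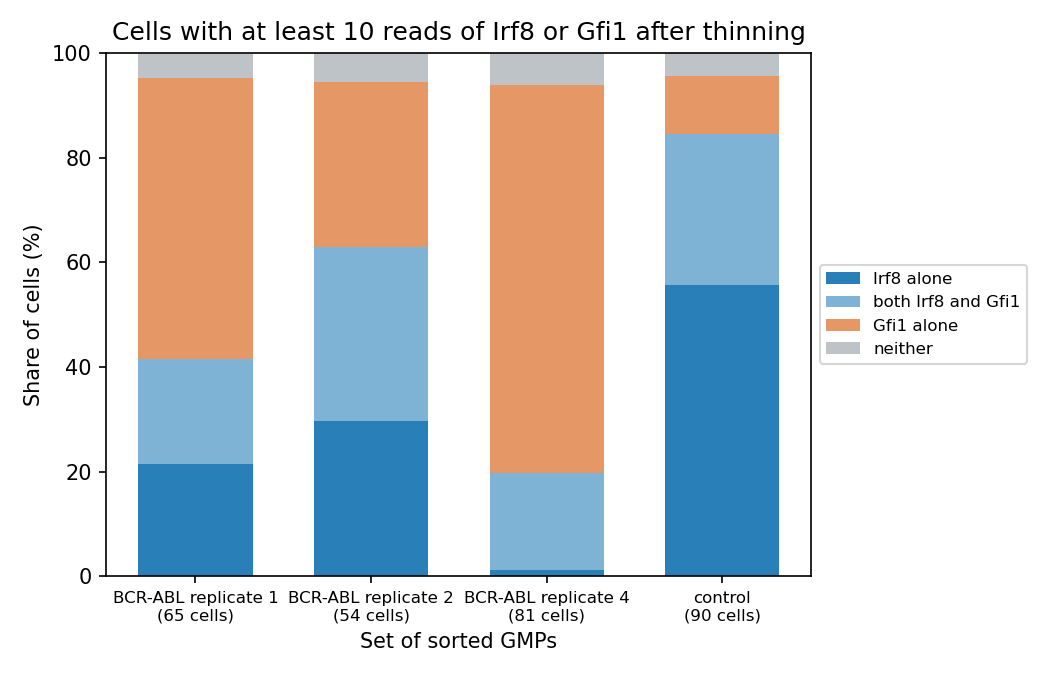
Share of thinned cells (%) in each set with at least 10 reads of Irf8 alone, Gfi1 alone, both or neither, as stacked bars. Gfi1 alone makes up 53.8, 31.5 and 74.1% of cells in BCR-ABL replicates 1, 2 and 4 against 11.1% in the control.

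Within neutrophil-like cells, Elane had a log2 fold change of 0.79 (SE 0.04, p = 8.51e-06, adjusted p = 0.146) and Lcn2 of 2.33 (SE 0.49). Meis1 stood at -2.12 (SE 0.32) and Cd34 at -1.24 (SE 0.48), while Gfi1 and Cebpe stood at -0.06 and 0.05. Of the 60 genes picked for the text, 55 were tested here: 17 had the opposite sign to that over all cells, 17 were smaller by more than 1.5 times, 9 larger and 12 within that range. Smaller were Lrg1 (1.21), Wfdc21 (0.96), Mpeg1 (-0.38) and Bcl2 (-0.13), among others. The sign was opposite for S100a8 (-0.26), Lyz2 (0.43), Ifitm1 (-0.77), Csf1r (2.33), Irf8 (1.13) and Ppfia4 (7.94, at 0.0 CPM in the control and under 1 in each BCR-ABL set), among others. The control holds 14 such cells, and markers of both classes were not kept out of the clustering that defined them, so signs of monocyte genes here may follow that selection. Of 17092 genes tested with edgeR, 0 were higher and 0 lower, 2308 had an unadjusted p under 0.05, and DESeq2 called 1299. No list passed fry there (smallest adjusted p = 0.48), and 11 of 35 passed its mixed form: stem, dendritic and p53 (0.0246 each), cytokine receptors, adhesion and glycolysis (0.037 each), megakaryocyte (0.0371), primary and late granule (0.0381 each), erythroid (0.0385) and Wnt (0.049). BCR-ABL replicate 4 holds too few monocyte-like cells for the same test. Without it, edgeR called 0 genes in monocyte-like cells (1267 at an unadjusted p under 0.05; DESeq2 366) and 0 for the interaction between class and condition (1442; DESeq2 492). Fewer sets enter here than in the main test, which recovered 9% of simulated genes changed by a log2 value of 1. The counts of 0 therefore say little. Monocyte-like cells were spread unevenly over clusters. The cluster with Ung and Ifitm1 among its leading genes held 14 of 22 and 17 of 28 such cells of replicates 1 and 2. In the control it held 5 of 73.

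Across cells of a set, the score of primary granule genes ran against that of monocyte genes, with Spearman rho of -0.419, -0.23 and -0.088 in the BCR-ABL sets and -0.442 in the control. It ran with late granule genes at 0.568, 0.699 and 0.738 against 0.395. Stem and early progenitor genes ran against primary granule genes in the BCR-ABL sets, at -0.229, -0.54 and -0.57, with 0.021 in the control. With monocyte genes they had -0.191 and -0.281 in BCR-ABL replicates 1 and 2, 0.083 in replicate 4 and -0.572 in the control. S phase genes had -0.209, -0.439 and -0.346 with primary granule genes, against -0.139, and G2/M genes -0.1, -0.098 and 0.056, against 0.032. Without thinning, the S phase values were -0.119, -0.241 and -0.215 against -0.186, so the control then lay within the BCR-ABL range. No test was run on these 6 relations.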

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

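All tests in this part were chosen after the result was seen, except that of wells sharing a library index, whose layout was itself read from Prg2 in BCR-ABL replicate 4. Wells with too few reads or genes were left out of every comparison, and they were more frequent in the BCR-ABL sets: 20.8%, 36.5% and 4.2% of wells in replicates 1, 2 and 4 against 2.1% in the control. Slc34a2, chosen after its values were seen, made up 10.1%, 19.3% and 6.43% of their gene reads in the BCR-ABL sets, against 0.043 to 0.074% in kept cells of the same sets. Failed wells had medians of 11346, 5921 and 7350 gene reads, against 1649313, 2084608 and 1385349 in kept cells. These shares therefore do not show more Slc34a2 reads per failed well, which was not compared. Carry-over from kept wells would bring their low share, so it would leave these reads unaccounted for.

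Reads from libraries of other sets should have brought 57.8 Xist reads to the 39 failed wells of replicates 2 and 4, and 0 were found; in replicate 1, 31.6 Y-linked reads should have come to 20 failed wells and 5 were found (16.9 CPM against 0.13 in kept cells), so a part there stays open. A failed reaction as the main cause should have lowered spike-in reads, whose medians in failed wells of the BCR-ABL sets were 1.43 to 2.06 times those of kept cells. It stays open for 4 of these 59 wells, with fewer spike-in reads than any kept well of their set and also fewer reads in total, as had 39 of the other 55, and in the 2 failed control wells the median was 453 against 6831. Carry-over between wells of a set remains a possible source: for 1 gene in each of 3 source wells, 98.2%, 86.7% and 100% of its stray reads lay in the 18 wells that share a run of well numbers, against 18.9% if spread evenly, and failed wells held a median of 0.73 to 1.34 times the reads expected at the rate seen for Prg2 in the BCR-ABL sets, and 1.73 times in the control. An empty well and a damaged cell could both leave spike-ins with at most a median of 11346 gene reads and cannot be told apart, so no biological explanation was tested.

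That carry-over result is thin and, by share of reads, partly contradicted. The read limit for source wells was lowered after 20000 and then 5000 left 0 and 1 sets with a source well, the gene in each was Prss34, and only the gene with most reads per well was counted. Of the genes left out of that count, 2 had most of their stray reads outside partner wells. Partner wells held 12.1% of the stray reads of Cyp11a1 in BCR-ABL replicate 2. They held 27.7% of those of Prg3 in BCR-ABL replicate 4, against 85.6% for Epx in replicate 4. Counted by wells, both genes followed the layout. Cyp11a1 had a read in 11 of 18 partner wells and 2 of 77 other wells, and Prg3 in 12 of 18 and 4 of 77.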

How the results depend on the processing

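Tests with detection filters, a second limma filter, 1 cell removed, BCR-ABL replicate 4 left out of class tests, clustering of thinned cells, or genes left out of clustering were chosen after the data had been seen; the other alternatives were not. No paired analysis was possible because the groups share only replicate number 1. Depth limits rare transcripts, such as Ccno with 10 control reads. edgeR kept 0 genes under 11 other settings, 1052 to 1735 of them at an unadjusted p under 0.05 except 983 with detection in 25% of cells. DESeq2 called 562, detection in 50% of cells gave 3 (Ccno higher, Gm28438 and Gm3786 lower), detection in 90% gave 2, and limma with the other filter 2. Within neutrophil-like cells, no filter on low counts gave 22 and DESeq2 1299. DESeq2 gave 366 in monocyte-like cells and 492 for the interaction. Lists passing mixed fry went from 2 to 0 with thinning or without the cell with most genes, to 1 with detection in 25% or 50% of cells, and 0 to 2 leaving out each replicate. Camera with a preset correlation went from 7 lists to 8 to 13 leaving out each replicate, and to 4 with detection in 25% or 90% of cells. The monocyte-like difference in share stayed between -60.9 and -43.1 points and the neutrophil-like one between 15.7 and 43, except with centring within sets (12.4 and -1.8), which removes set means. Mean rho of S phase with primary granule genes went from -0.331 to -0.192 without thinning, that of stem with monocyte genes from -0.13 to -0.026 and of G2/M with primary granule genes from -0.047 to 0.026, the last 2 within the spread between sets. Of 593 values for the 60 picked genes, 555 stayed, 34 passed under DESeq2 and 4 reversed: Fcgr3 without replicate 1 (-0.01, range -0.01 to 0.15), Spi1 thinned (0.01) and without replicate 1 (0.01, range -0.03 to 0.01), and Epx without replicate 4 (-0.31, range -0.31 to 8.31). Of 1455 values for all 151 genes, 6 reversed. That a value rounding to 0.00 has no direction was decided after the values were seen, and without it 9 and 11 would reverse, Mpo (-0.03 to 0.08) and Ctnnb1 among them. Centring also left most cells without a name, and why values moved was not tested. Not run were class tests without a filter on cells and the interaction as planned.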

Other observations

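All tests in this part were chosen after the result was seen, except that of the chromosome 15 window with other single sets. Gm28438 and Gm3786, predicted genes chosen after their values were seen, had a read in 98.9% of control cells each, against 19.6 to 37.7% and 7.6 to 13.1% of BCR-ABL cells. Prg2, a protein of eosinophil granules, had 130771 reads in 1 cell of BCR-ABL replicate 4. Another cell of that set had reads on 19454 genes, against 11679 in the next, and 39.4% of its reads lay outside features.

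The lower monocyte-like share of the BCR-ABL sets was set against 3 explanations. Were depth the cause, the difference would vanish when thinned cells are clustered, yet the control share was then 68.9% against 1.2 to 16.7%, with 21 to 40.7% of BCR-ABL cells and 11.1% of control cells unnamed. Loss of monocyte-like cells into failed wells cannot make up the whole difference in replicates 1 and 4. Counting every failed well as monocyte-like gives an upper bound of 54.3% there, against 66.3% as the lower bound of the control. It may do so in replicate 2 (75%). A part stays open in replicate 1, which would rise to 43.8% of wells, and the bounds cover counting error only. Sex alone would give the 2 sets with Xist the same share, but the 1 BCR-ABL set with Xist lies -48.8 points from the control. Sex and condition are partly confounded: the control set has Xist, and both sets nearly without it, replicates 2 and 4, are BCR-ABL. Sex may still contribute, because 1 set with Xist per condition cannot separate it from other differences between sets. BCR-ABL itself remains among the open explanations, and a plate, litter or animal peculiar to the 1 control set has not been tested.

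The number of genes at an unadjusted p under 0.05 does not stand apart. Of the 4 ways to set 1 set against 3, 2 gave as many genes: 1459 for the control and 1650 for BCR-ABL replicate 4, with 609 and 842 for the others. These 4 splits are too few for a share under 0.05. With detection in 25% of cells the control again had fewer (983) than replicate 4 (1229), while DESeq2 called 562 and 514.

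Low p-values gathered on chromosome 15, where 10 of 84 genes between 77.5 and 82.5 Mb had a p under 0.01, against 172 of 11749 overall. Of random placements 0.0002 gave as extreme a window, and 7 scans were tried: with a limit of 0.05 the share was 0.232 or 0.326 and another chromosome led, and within neutrophil-like cells the leading window began at 75 Mb, with a share of 0.514 or 0.0524. Were the window to differ in any set, a BCR-ABL set against the rest should show a like excess, but none did (smallest binomial p = 0.133). By a binomial count such an excess would be seen with a chance of 0.98 in replicate 4, against 0.175 and 0.324 in replicates 1 and 2. These chances leave out that the control set lies among the rest in each such split. Genes that set the control apart then vary widely within the rest and can hardly reach a low p. This test therefore cannot decide whether the window differs in any set. A shift in cell classes would have to shrink the differences, which kept 0.86 of their size in neutrophil-like cells, with 9 of 10 in the same direction. A strain-derived or transgene-linked interval may underlie the 10 genes, 7 higher and 3 lower, but counts per gene hold no sequence, so this cannot be told apart. Among them are Ncf4, Rpl3 and Cyth4, of which Cyth4, chosen after its values were seen, turned from -0.63 to 1.43 in neutrophil-like cells.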
